A study of Mus musculus with 6 samples.

How the data were processed

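The series holds 6 RNA-seq libraries from cells labelled SaOS2, an established human osteosarcoma cell line. Their titles carry the letter C or D with a number from 1 to 3, and these letters were used as the 2 groups, with 3 libraries in each. No label spells out the letters, so every difference is given as D minus C and neither group is called treated or untreated. No label says whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries only, which may be technical. Per the labels' protocols, total RNA was purified with a column kit and libraries were made with a SMARTER kit for mRNA. The aligner, the counting program and the strand setting are not given in the sources used here.

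For each library the authors deposited gene counts, which are whole numbers listed by gene symbol without normalization. The authors also deposited FPKM values for the same genes. Each FPKM value equalled the count divided by the total count of the library and by a gene length that was the same in all 6 libraries for 17144 of 17144 genes, within a relative tolerance of 0.001. The implied length was a whole number of base pairs for all of them, within 0.01 bp, with a median of 3789.5 bp, and these lengths were used wherever gene length enters. Every listed gene had at least 1 count over the 6 libraries, and 0 mitochondrially encoded symbols were listed.

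The labels name the mouse as the organism, and the submitters' processing notes name the mouse builds GRCm38 and mm10. The symbols in the files follow human naming. Of the 17144 symbols, 14 matched a mouse symbol exactly in letter case. The reference supplied with the series was a mouse genome and was used only for that match. Genes are therefore identified by the symbols in the files, and no coordinates are given.

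Library totals ranged from 18446443 to 20602771 counts, and the mean totals of the groups differed by 2.72%. A floor of 3 counts corresponded to 0.146 to 0.163 CPM (counts scaled to a common library total). Floors cover counting error only, since reads without molecular identifiers are not independent molecules. In every pair of libraries within a group the values differed by more than sampling noise: the chi-square statistic per degree of freedom ranged from 6.46 for C replicates 1 and 2 to 95.43 for D replicates 2 and 3.

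Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 12682 genes and 99.952% of the counts and left out 4462 genes. Libraries were scaled with TMM factors, and the quasi-likelihood F test of edgeR was applied, 2-sided, with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a second count required a change of at least 2-fold. The standard error of a log2 fold change was its size divided by the square root of F. Values per library are TMM-normalized CPM, given as mean ± SD with n = 3. No fitted fold is printed for a gene with a mean of at most 3 counts over the C libraries.

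Gene lists were fixed before the data were examined: 25 programs and 7 sets of markers of other cell types. The 30 lists with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. The list of mitochondrially encoded genes had no listed member, and the hematopoietic and lymphoid markers had 2 tested members, so neither was tested as a list. Named genes were chosen by a rule fixed beforehand. It took, among called genes with a mean log2 CPM of at least 3 whose D libraries all lay above or all below the C libraries, the 8 with the largest change and the 5 with the lowest p in each direction. It added up to 2 called members per direction from each list, or the member with the lowest p where none was called, and genes for the identity of the line, of which RB1, RUNX2, ALPL and COL1A1 were used. The rule gave 108 genes. It passed over 1 gene with a provisional symbol.

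The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, upper quartile factors, library size only, no filter on low counts, a minimum of 1 CPM in 3 libraries, an adjusted p under 0.01, the replicate number as a block, each library left out in turn, the 20 most abundant genes left out, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), with FPKM above 1 in at least 3 libraries or without that filter. For the lists they were camera with an estimated correlation and fry. After the data had been seen, an alternative was added that removes the trend of each library with gene length by a lowess curve with a span of 0.4.

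The tests were tried on simulated counts with the mean values of the C libraries and the library sizes of all 6 libraries. Both simulated groups were given the same spread for each gene. In the data, the spread between libraries beyond counting noise (biological coefficient of variation) was 0.0752 in C and 0.189 in D. The simulation does not reproduce that difference. For the D against C comparison over 12417 simulated genes, edgeR recovered 17.2% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 96.8% of those changed 4-fold, and 7.14% of its 140 calls were unchanged genes. Few genes were changed in the simulation, so a gene needed a lower p to be called than in the real data. For the list test over 12682 genes, a list of 25 genes raised 1.5-fold was called and 0 of the unchanged lists were called. Simulated genes varied independently, so this cannot show how the test behaves where the genes of a list vary together. The estimated correlation of the ribosomal protein list was 0.98. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.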

Results

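Messenger RNA was measured by RNA-seq in 6 libraries of cells labelled SaOS2, an established human osteosarcoma line, with 3 libraries in group C and 3 in group D. The series title concerns the effect of a compound named DDTC(I) on these cells, and the comparison of D with C addresses which messenger RNAs differ between the groups. No label gives the meaning of C or D. Total counts per library were 18532763, 20602771 and 19943387 in C and 18446443, 19802340 and 19263689 in D. Between 15174 and 15259 genes had at least 1 count in the C libraries, and between 15444 and 15547 in the D libraries. The 20 most abundant genes of each library held 9.31% to 9.67% of the counts in C and 11.11% to 11.83% in D. Counts are deposited whole numbers per gene symbol, and the values below are normalized CPM (counts scaled to a common library total), as mean ± SD with n = 3 per group.

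Markers of the species and of the line were read in every library. Of 14 human genes without a close mouse counterpart, 14 were listed and 11 had more than 3 counts in every library, and 0 of 18 mouse genes without a close human counterpart were listed, although the labels name the mouse. Because the files use human naming, the absence of mouse genes does not bear on the species of the cells. ALPL, the alkaline phosphatase of osteoblasts, for which SaOS2 is known to have high activity, had 8 to 15 counts per library. This low level goes against the SaOS2 label, so the identity of the cells is in doubt and they are named here by their label. The log2 fold change of ALPL, 0.31 ± 0.33, did not pass the test (adjusted p = 0.45, edgeR). RB1 had 35.8 ± 1.36 CPM in C and 47.8 ± 11.7 in D, and its log2 fold change of 0.42 ± 0.17 did not pass the edgeR test (adjusted p = 0.063). Without D replicate 3 the log2 fold change of RB1 was 0.56 and passed it (adjusted p = 0.0014, edgeR), and it also passed in DESeq2 (0.43), with RLE factors (0.44) and with length trends removed (0.48). RUNX2, a transcription factor of the bone lineage, fell from 19.6 ± 1.73 to 9.14 ± 1.97 CPM (log2 fold change −1.10 ± 0.17).

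Metallothionein genes, heat shock genes and the heme oxygenase gene were among the largest rises in D, and genes of cell division among the largest falls. HSPA6, an inducible HSP70 chaperone, rose from 3.46 ± 0.575 to 419 ± 116 CPM, a log2 fold change of 6.92 ± 0.26 (SE). HMOX1, which encodes heme oxygenase, rose from 175 ± 4.12 to 4679 ± 790 CPM (4.74 ± 0.16), and the metallothionein MT1E from 80.9 ± 3.62 to 2370 ± 673 CPM (4.87 ± 0.23). KIF20A, a kinesin of cell division, fell from 265 ± 12.1 to 28.8 ± 2.72 CPM (−3.21 ± 0.11). The adjusted p was 2.1e-06 for HSPA6, HMOX1 and KIF20A and 4.9e-06 for MT1E in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

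Of 12682 genes tested, 6902 passed an adjusted p of 0.05 in that test, 3393 higher and 3509 lower in D. At least a 2-fold change was found for 2346 of them, 1062 higher and 1284 lower. Of all tested genes, 26.8% were called higher and 27.7% lower, the shares to set beside the counts of list members below. The share of calls that were higher was 49.2%, and it was 36.8% with library size only (2586 higher and 4449 lower), a scaling under which the median log2 change of all genes was −0.17 in place of −0.02. The share also varied with gene length, from 73.2% of the calls in genes of up to 1500 bp (median log2 change 0.251) to 35.2% in genes over 6000 bp (−0.203), and without D replicate 3 from 59.1% (0.079) to 44.3% (−0.080). With the length trend of each library removed, which evens these shares by construction, they were 52.7% and 51.3%. No label says that the 3 libraries of a group are separate cultures, so each p measures only the spread between these libraries.

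Among called genes with a mean log2 CPM of at least 3, the other largest rises were in MT1X (log2 fold change 4.93), HSPA1A (4.81), HSPA1B (4.65), FOS (4.54) and MT2A (4.45), with standard errors between 0.17 and 0.27. HSPA1A and HSPA1B are near-identical copies, as are several metallothionein genes, so the division of reads between such copies is uncertain. Among the lowest p-values were also those of the chemokine gene CXCL8, which rose from 2.13 ± 0.247 to 40.3 ± 3.13 CPM (4.24), of PPP1R15A, a regulator of the eIF2 phosphatase (3.77), and of the epithelial splicing factor gene ESRP1 (4.06). Among the same genes, the largest falls after KIF20A were in CYP24A1, a vitamin D hydroxylase, from 31.6 ± 5.83 to 3.46 ± 0.48 CPM (−3.19 ± 0.18), and TXNIP, a thioredoxin-binding protein gene, from 578 ± 159 to 63.9 ± 8.2 CPM (−3.18 ± 0.22). E2F8 (−3.10), TNFAIP8L1 (−3.10), CCNF (−2.92), MKI67 (−2.82) and PSRC1 (−2.76) followed. MKI67, a proliferation marker, had the widest error of these (0.39), with 373 ± 63.5 CPM in C and 52.8 ± 30.6 in D. FAM83D (−2.63), MAGED1 (−2.51) and the cell cycle inhibitor gene CDKN2C (−2.72) were among the falls with the lowest p. Each gene in this paragraph had all 3 D libraries on the same side of all 3 C libraries, as the rule that named it required.

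**Figure D1:**
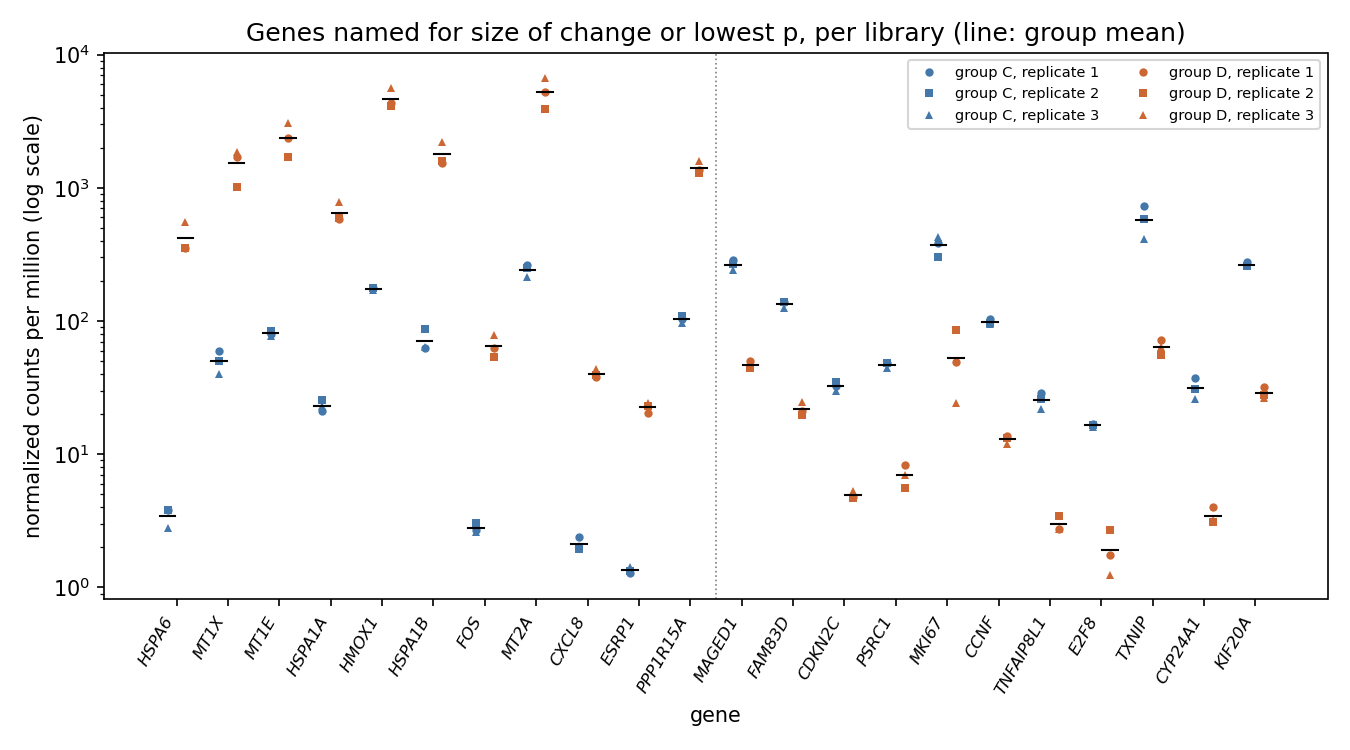
Normalized CPM on a log axis for the genes with the largest changes and the lowest p-values, with a point for each of the 3 C and 3 D libraries and a line at each group mean. The D libraries of HSPA6, MT1E and HMOX1 lie above the C libraries, and those of KIF20A, CYP24A1 and TXNIP lie below them.

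Metallothionein, heat shock, NRF2 target, proteasome and autophagy genes rose as groups. Of 6 tested metallothionein and zinc export genes, 6 rose, with a median log2 fold change of 4.90, among them SLC30A1, a zinc exporter, from 32.1 ± 1.78 to 356 ± 65 CPM (3.47 ± 0.15). MT1G and MT1B had a mean of at most 3 counts in C and reached 6.99 ± 2.59 and 11.6 ± 4.37 CPM in D. Of 24 heat shock genes, 20 rose and 0 fell (median 1.02), and of 26 targets of NRF2, the regulator of antioxidant genes, 20 rose and 0 fell (median 1.40), OSGIN1 from 28.8 ± 1.93 to 221 ± 20.4 CPM (2.94 ± 0.12). Without D replicate 2, 23 NRF2 targets rose and 2 fell, and 20 heat shock genes rose and 1 fell. Of 31 proteasome subunit genes, 31 rose (median 1.03), including PSMD12 (1.57 ± 0.11) and PSMD1 (1.16 ± 0.10). All 31 also rose with length trends removed (median 0.934). Of 30 autophagy and lysosome genes, 21 rose and 1, TFEB, fell (−0.80), against 18 and 4 with library size only, while the receptor gene SQSTM1 rose from 489 ± 13.8 to 2519 ± 240 CPM (2.36 ± 0.12) and GLA, a lysosomal galactosidase, by 2.11. Counts adjusted over the list alone were the same here and for the lists in the paragraphs that follow, except where given, and the NRF2 targets had 22 higher. The camera test with a preset correlation gave adjusted p-values of 5.0e-06 for the metallothioneins, 1.9e-08 for heat shock, 3.0e-09 for NRF2, 1.9e-11 for the proteasome and 1.5e-05 for autophagy. With an estimated correlation these were adjusted p = 0.17, 0.37, 0.14, 0.37 and 0.37, so no call held. The mean log2 CPM of the proteasome genes lay above the C mean by 0.996, 0.856 and 1.267 in D replicates 1, 2 and 3. The D libraries also differed along gene length. For this, log2 CPM was taken as each library's deviation from the D mean. Its slope on log2 length was 0.0126, 0.1704 and −0.183 in D replicates 1, 2 and 3.

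Genes of the integrated stress response rose, while those of the endoplasmic reticulum chaperone list went both ways. Of 27 genes of the ATF4 and integrated stress response list, 24 rose and 1, VLDLR, fell (median 1.61). SESN2, a stress-induced regulator of growth signalling, rose from 50.5 ± 2.81 to 357 ± 19.4 CPM (2.82 ± 0.11), and ATF4 itself by 1.25 ± 0.14. The camera adjusted p of this list was 1.9e-11, and it was adjusted p = 0.14 with an estimated correlation. The endoplasmic reticulum chaperone list also holds genes that are not chaperones, such as the transcription factor gene XBP1. Of its 22 genes, 6 rose and 6 fell (adjusted p = 0.70, camera), and with library size only 5 rose and 11 fell. XBP1 (1.41) and DNAJB9 (1.36) rose, and SDF2L1 (−1.45) and PDIA4 (−0.86) fell. VLDLR had a log2 fold change of −0.61, and its call was lost without C replicate 1 (−0.62), without C replicate 3 (−0.50) and without D replicate 1 (−0.64). The call was also lost with the replicate number as a block.

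Genes of mitosis fell together, while genes of DNA replication moved less. Of 29 mitosis genes, 29 fell, 27 of them at least 2-fold (median −1.49), including PLK1, a mitotic kinase, from 358 ± 8.78 to 73.0 ± 7.04 CPM (−2.29 ± 0.11). The camera adjusted p was 2.0e-13, and adjusted p = 0.12 with an estimated correlation. Of 30 replication genes, 5 rose and 9 fell (median −0.15; adjusted p = 0.41, camera), and with library size only 4 rose and 14 fell (median −0.30). Thymidylate synthase TYMS (−0.82) and the ribonucleotide reductase subunit RRM2 (−0.58) fell, while RPA2 (0.51) and MCM7 (0.46) rose. The mean log2 CPM of the mitosis list exceeded that of the replication list by 1.503 ± 0.161 in C and 0.041 ± 0.072 in D (SD, n = 3; exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of 29 DNA damage and repair genes, 1 rose and 8 fell (adjusted p = 0.54, camera; 1 and 7 adjusted over the list alone), among the falls RAD54L (−0.95) and H2AX (−1.05). The share that fell was near the 27.7% of all tested genes called lower. The rise of XRCC5 (0.35) was not called with library size only (0.20), without C replicate 1 (0.33) or without C replicate 3 (0.33). Its call was also lost with the replicate number as a block. Without D replicate 3, 7 of these genes rose and 8 fell, and without D replicate 2, 3 rose and 12 fell.

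Regulators of apoptosis and ferroptosis went both ways. Of 27 apoptosis genes, 10 rose and 5 fell (adjusted p = 0.41, camera), and with library size only 7 rose and 7 fell. The survival gene MCL1 (1.11 ± 0.10) and the pro-apoptotic gene PMAIP1 (1.05 ± 0.11) rose, and the apoptosome gene APAF1 (−1.56 ± 0.17) and BAK1 (−0.71 ± 0.14) fell. Of 20 ferroptosis-related genes, 10 rose and 5 fell (10 and 6 adjusted over the list alone; adjusted p = 0.13, camera). AIFM2 (1.78) and KEAP1 (1.49) rose, and the lipid enzyme genes LPCAT3, from 34.8 ± 1.61 to 17.4 ± 1.09 CPM, and ACSL3 (−0.69) fell.

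Immediate early and inflammatory genes rose. Of 27 immediate early genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone; median 1.11), with EGR1 rising from 1.91 ± 0.172 to 37.7 ± 5.52 CPM (4.30 ± 0.17) and FOSL2 (−0.82) and KLF6 (−0.71) falling. Of 21 NF-kB inflammatory genes, 15 rose and 1, the growth factor gene CSF1, fell (−0.93), and the median was 0.85. The chemokine gene CXCL3 rose from 0.835 ± 0.0385 to 10.4 ± 1.49 CPM (3.63 ± 0.19), and IL1A, with a mean of at most 3 counts in C, reached 1.21 ± 0.238 CPM in D. Of 26 interferon-stimulated genes, 14 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.55), IFI44 (1.86) and RSAD2 (2.10) rising and GBP2 (−1.07) falling. The camera adjusted p-values were 9.2e-07 for the immediate early, 2.0e-06 for the NF-kB and 0.0029 for the interferon list. With an estimated correlation these were adjusted p = 0.15, 0.14 and 0.14.

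Genes of ribosomes rose and genes of cholesterol synthesis fell. Of 52 cytosolic ribosomal protein genes, 50 rose and 0 fell (51 adjusted over the list alone; median 0.68), including RPS9 (0.97 ± 0.18). With length trends removed, 50 also rose (median 0.478). With library size only 42 rose, and with the replicate number as a block 37 rose. These genes have many processed pseudogenes that can share their reads. Of 26 ribosome biogenesis genes, 14 rose and 0 fell (15 adjusted over the list alone; median 0.57), against 18 without D replicate 2, 18 without D replicate 3 and 22 with length trends removed, RRP12 by 1.57 and NOP58 by 1.44. Of 24 cholesterol synthesis genes, 16 fell (17 adjusted over the list alone) and 1, SREBF1, rose (0.98). Squalene epoxidase SQLE fell from 153 ± 13.6 to 47.4 ± 2.45 CPM (−1.69 ± 0.11), and the sterol carrier gene STARD4 by 1.38. The camera adjusted p-values were 1.5e-08 for ribosomal proteins, 1.7e-05 for ribosome biogenesis and 0.00080 for cholesterol synthesis, and with an estimated correlation adjusted p = 0.58, 0.37 and 0.37.

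Of 44 nuclear genes of oxidative phosphorylation, 8 rose and 1, SDHA, fell (4 and 1 adjusted over the list alone; median 0.23). NDUFB9 (0.91) and NDUFA4 (0.81) rose, and SDHA fell from 341 ± 10.5 to 202 ± 5 CPM (−0.75 ± 0.09). The camera adjusted p was 0.046, and adjusted p = 0.78 with an estimated correlation. With library size only 5 rose and 3 fell. Without D replicate 3, 6 rose and 4 fell with a median of 0.07 (adjusted p = 0.44, camera), without D replicate 2, 27 rose and 1 fell, and without C replicate 3 the camera adjusted p was 0.21. The mean log2 CPM of these short genes relative to C was 0.18, −0.05 and 0.53 in D replicates 1, 2 and 3, and that of the ribosomal protein genes 0.61, 0.36 and 1.03. Of 30 hypoxia and glycolysis genes, 11 rose and 7 fell (adjusted p = 0.40, camera), and with library size only 7 rose and 8 fell. With the replicate number as a block, 7 rose and 5 fell. The angiogenic factor VEGFA rose from 99.3 ± 5.06 to 401 ± 15.3 CPM (2.01 ± 0.10) and NDRG1 by 1.13, and ADM (−1.07) and PFKFB4 (−0.66) fell. Of the 27 symbols on the list of mitochondrially encoded genes, some of them alternative names of the same gene, 0 were in the count tables.

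Bone and matrix genes went both ways, with more falls than rises. Of 13 tested osteoblast genes, 4 rose and 6 fell (adjusted p = 0.57, camera). The collagen I genes COL1A1, from 23.3 ± 0.963 to 4.96 ± 0.585 CPM (−2.23 ± 0.13), and COL1A2, from 176 ± 27.3 to 49.9 ± 2.15 CPM (−1.82 ± 0.13), fell. SPP1, the osteopontin gene, rose from 0.341 ± 0.219 to 2.38 ± 0.659 CPM (2.79 ± 0.43), and ATF4, which is also on the stress list, was another rising member. Of 36 matrix and mesenchymal genes, 6 rose and 17 fell (adjusted p = 0.084, camera), among them ITGA5, an integrin subunit (−1.45 ± 0.13), and CCN1 (−1.31 ± 0.10) falling, and the transcription factor genes SNAI1 (1.15) and SNAI2 (0.79) rising.

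**Figure D2:**
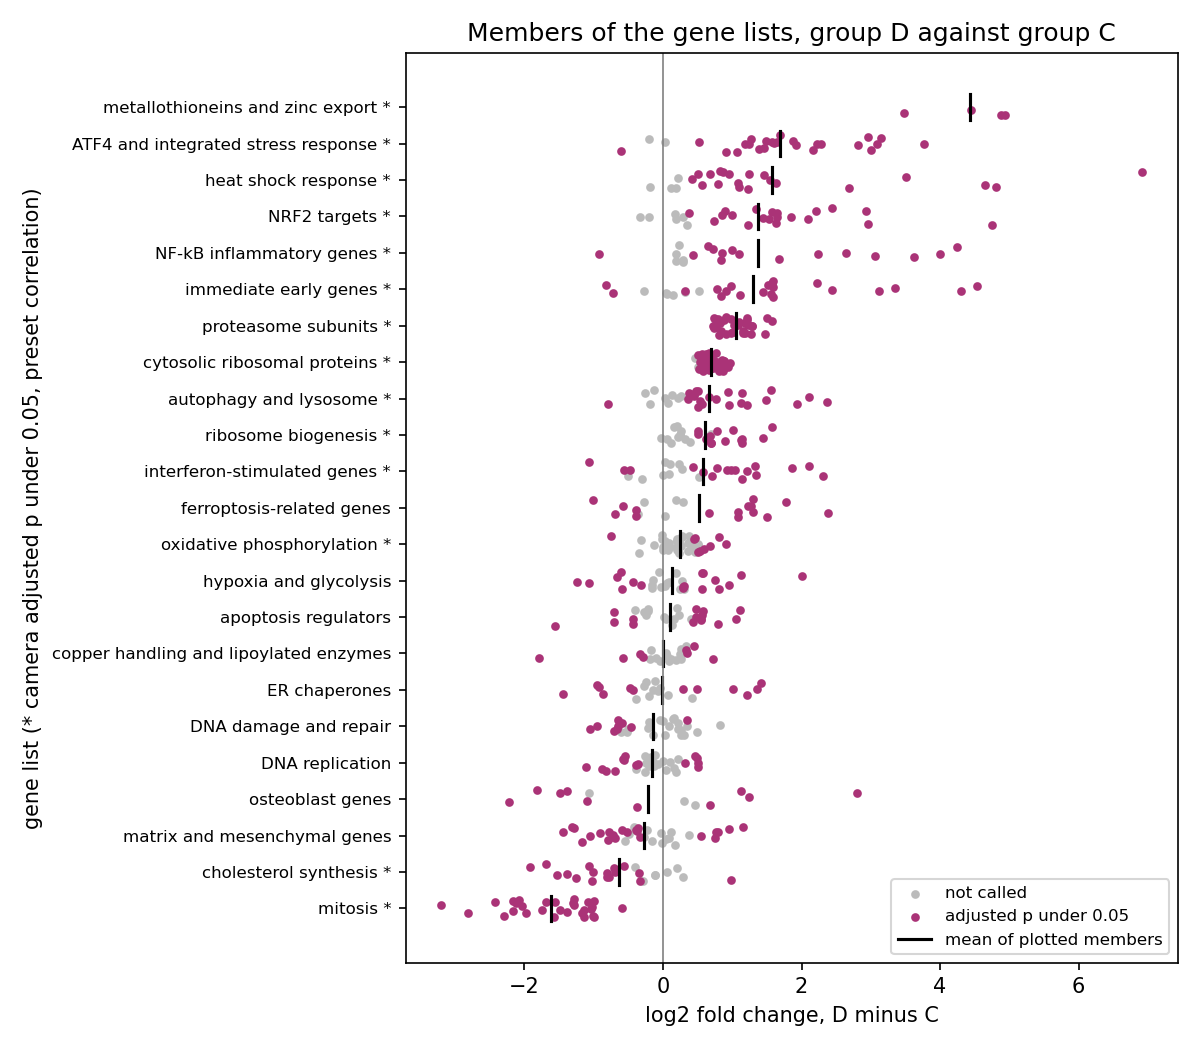
Log2 fold change, D minus C, on the horizontal axis for each tested member of the program lists described in the text, with a bar at the mean of the plotted members and an asterisk for a camera adjusted p under 0.05. Genes with a mean of at most 3 counts in C are left out, and the 29 mitosis genes all lie below 0 while the 31 proteasome genes all lie above it.

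Copper genes and markers of other cell types held called genes in both directions, and none of these lists that was tested passed the camera test. Of 21 copper handling and lipoylated enzyme genes, 4 rose and 4 fell (adjusted p = 0.70, camera), SOD1, the copper-zinc superoxide dismutase, rising by 0.72 ± 0.16 and the copper transporter gene ATP7B falling by 1.79 ± 0.21. Their median was 0.08, their mean −0.00, and with library size only 1 rose and 5 fell with a median of −0.08. With the replicate number as a block, 2 copper genes rose and 1 fell. The macrophage and osteoclast markers had 3 of 9 higher and 1 lower (adjusted p = 0.30, camera), with DCSTAMP rising by 2.73 and CD163 reaching 1.39 ± 0.225 CPM. The fall of ADGRE1 (−0.42) was not called without C replicate 1 (−0.39), without C replicate 2 (−0.43) or with the replicate number as a block. The endothelial markers had 0 of 7 higher and 2 lower (1 adjusted over the list alone; adjusted p = 0.56, camera), CDH5 falling by 2.93. PECAM1 fell by 0.44 and was not called without C replicate 1 (−0.46), C replicate 2 (−0.28), D replicate 1 (−0.38) or D replicate 2 (−0.40), in DESeq2 (−0.42), in limma-voom (−0.42) or with length trends removed (−0.25). The epithelial markers had 3 of 6 higher, with ESRP1 rising from 1.35 ± 0.0705 to 22.6 ± 2.14 CPM (4.06 ± 0.15) and KRT18 by 0.90, and 1 lower, CLDN4 (−1.96), with a mean of 0.82 and a camera adjusted p of 0.24. The chondrocyte markers had 1 of 4 higher, COL11A2 (1.53), with a median of −0.09, a mean of 0.24 and a camera adjusted p of 0.70. Among 6 muscle markers, MYH3 (1.28) and TAGLN rose, and DES (−1.60) and ACTA2 (−0.70) fell, with a median of 0.04, a mean of −0.08 and a camera adjusted p of 0.87. TAGLN had a log2 fold change of 0.43 and was not called with library size only (0.28) or without C replicate 1, 2 or 3 (0.43, 0.43 and 0.42). Of 3 adipocyte markers 0 passed the edgeR test, 0 had an unadjusted p under 0.05 and 0 passed in DESeq2 or limma-voom (adjusted p = 0.68, camera), and FABP4 had a log2 fold change of −0.69, which was −1.07 and passed the test without D replicate 3. With library size only, and with length trends removed, 1 of the 3 adipocyte markers was called lower. Of 2 tested hematopoietic and lymphoid markers, SPI1 reached 1.07 ± 0.128 CPM from a mean of at most 3 counts in C, and CD34 fell by 1.25.

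Of the 30 lists tested, of which 1 without a call is not described here, 14 passed with the preset correlation, 12 higher and 2 lower in D, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. With fry, which tests whether the genes of a list move on balance one way (directional) or change either way (mixed) and compares the list with no other genes, 23 and 29 lists passed.

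**Figure D3:**
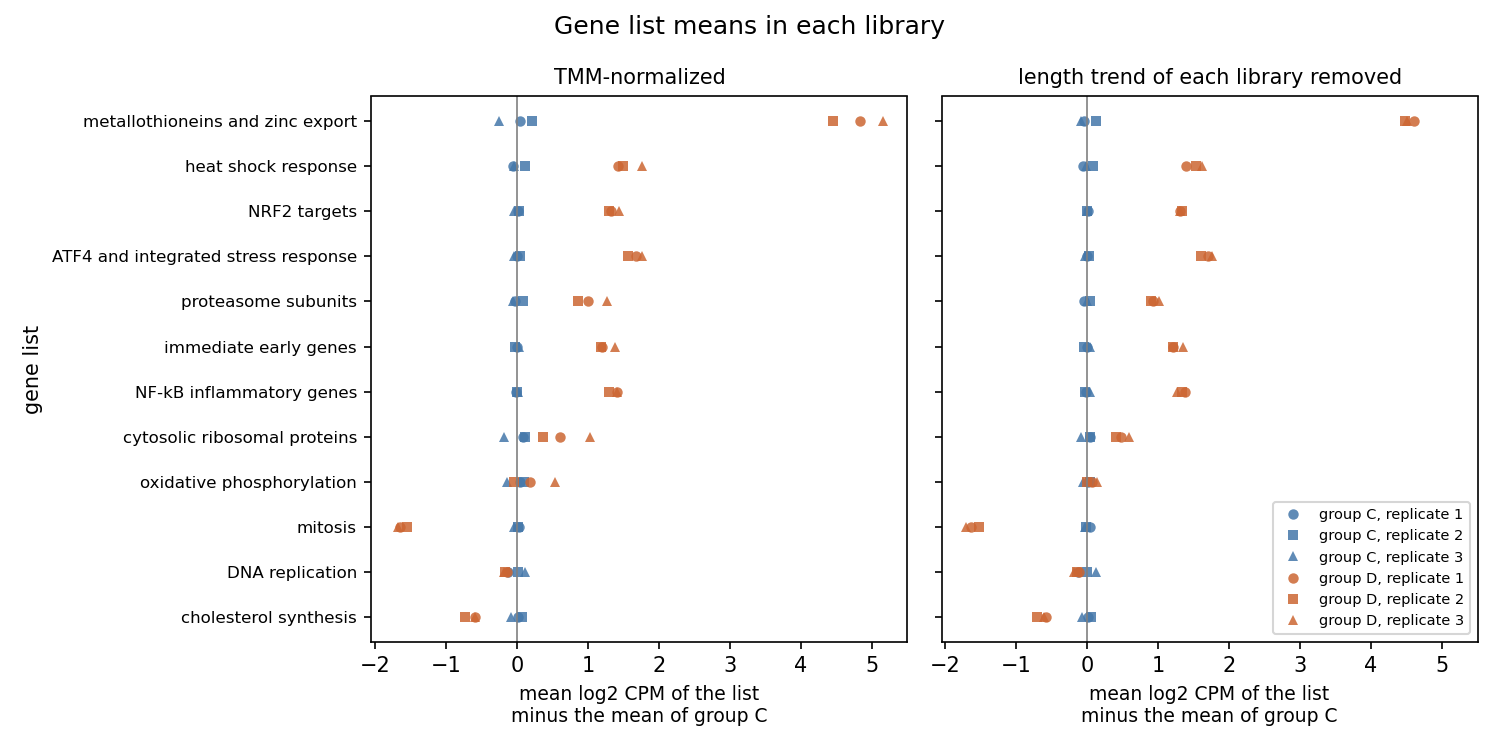
Mean log2 CPM of selected gene lists (vertical axis) per library, minus the mean of the C libraries (horizontal axis), with normalization factors alone in the left panel and with the length trend of each library removed in the right panel. The mitosis means of the 3 D libraries lie between −1.671 and −1.554, and the oxidative phosphorylation means of D replicates 2 and 3 lie at −0.05 and 0.53 before the trend is removed.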

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

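The removal of gene length trends and the counts of list members without single D libraries were chosen after the results were seen, and the other alternatives before the data were examined. Genes called numbered 6902, and between 4865 (adjusted p under 0.01) and 8023 (length trend removed) under the alternatives. They numbered 5407, 5634 and 5600 without C replicate 1, 2 or 3. Without D replicate 1, 2 or 3 they numbered 5705, 7767 and 7705. Genes changed at least 2-fold numbered 2313 to 2686 with a library left out. The biological coefficient of variation was 0.0752 in C and 0.189 in D, while the edgeR fit used the same dispersion of a gene for both groups. No named gene and none of the 14 called lists changed direction. Among lists without a call, the mean log2 fold changes of the copper and endoplasmic reticulum chaperone lists (−0.005 and −0.015) took either sign across settings, and those of the apoptosis and hypoxia lists fell below 0 with library size only, which lowers all genes alike. The FPKM tests gave fewer higher genes (2213 with a pseudocount of 1 and 2209 with 0.1). With log2(FPKM + 1), 1057 genes changed at least 2-fold, 365 higher and 692 lower, and 1061, 368 and 693 without the filter, while log2(FPKM + 0.1) gave 1740, 508 and 1232. FPKM carry no scaling beyond the library total. Their median log2 change was −0.14 with a pseudocount of 1, −0.17 with 0.1 and −0.12 with 1 and no filter. A pseudocount of 1 also shrinks the folds of low values. The rest of the cause was not tested. Of 30 gene lists, 14 were called with the preset correlation, 0 with an estimated one (7 at an unadjusted p under 0.05), 23 with directional and 29 with mixed fry, which ask another question. The oxidative phosphorylation call (adjusted p = 0.046) was also lost with library size only (0.10), without C replicate 3 (0.21), without D replicate 3 (0.44) and with length trends removed (0.67). With the replicate number as a block, 5671 genes and the same 14 lists were called, and 6 named genes lost their call, among them XRCC5, VLDLR and ADGRE1. Deviations of same-numbered libraries correlated at 0.0084, −0.40 and −0.37, and C replicate 2 correlated best with D replicate 3 (0.42). Those libraries both had negative length slopes (−0.0492 and −0.183), so the correlations do not separate pairing from length trends. They cannot tell whether same-numbered libraries shared a culture or day. The calls of ADGRE1, GCSH, PECAM1, SLC31A1, STAT2, TAGLN, VLDLR and XRCC5 were each lost in at least 1 alternative, that of STAT2 without C replicate 1 (−0.42) and that of GCSH without C replicate 1 or 2 (−0.56 and −0.48) or D replicate 1 or 2 (−0.56 and −0.39). A change of 1.5-fold was recovered for 17.2% of simulated genes. The simulation gave 140 calls against 6902 here, so a simulated gene needed a lower p to be called. That share is therefore not the power of the present comparison, and a gene without a call is still not shown to be unchanged.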

Other observations

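The gene families and the tests of sample splits, gene length trends and species labels here were chosen after the results were seen; the tests of the extent of change and of proteasome assembly genes were set before their values were seen. Genes for charging transfer RNA and acidifying lysosomes were called higher more often than lower in D, against 26.8% higher and 27.7% lower among all tested genes, and no enrichment was tested. Of 18 cytosolic tRNA synthetase genes, 13 were higher and 0 lower in D (median log2 fold change 0.77; 11 higher and 1 lower with library size only), among them GARS1 (1.48) and TARS1 (1.33). Of 19 genes of the vacuolar proton pump, 13 were higher and 3 lower, ATP6V1C1 by 1.40. The matrix metalloproteinase genes had 8 of 14 higher and 3 lower, MMP1 by 2.17 and MMP3 by 2.20.

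Some families of cytoskeleton, adhesion and Wnt signalling genes had more members called lower than higher in D, against 27.7% lower among all tested genes. Of 15 tubulin genes, 11 were lower and 1 higher (median −0.74), among them TUBB (−0.74) and TUBB4A (−2.51), and of 30 kinesin genes, among them members of the mitosis list, 14 were lower and 1, KIF7, higher. With library size only 17 kinesin genes were lower and 0 higher, and without D replicate 3, 14 and 4. Integrin genes had 10 of 23 lower and 2 higher, ITGA6 falling by 1.22, and laminin genes had 6 of 12 lower and 2 higher, LAMC1 falling by 0.98. Of 18 Wnt and Frizzled genes, 12 were lower and 1 higher, with FZD4 (−1.21) and WNT7B (−1.11) lower and FZD8 (1.05) higher.

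A hypothesis was that proteasome assembly factors and p97 cofactors rose with the proteasome subunits. Of 29 such genes tested, 20 were higher and 0 lower in D, a share of 69% against 26.8% of all tested genes, with a median log2 fold change of 0.52. With library size only 16 were higher and 5 lower, and without D replicate 3, 20 and 2. ADRM1 (1.81), ZFAND5 (1.48) and the p97 gene VCP (0.64) were higher, while NFE2L1 had −0.29 and DDI2 −0.04.

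The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. Every split other than the real one placed C and D libraries together on both sides. The difference between the groups then counted as spread within a side, so few called genes there were built in. The splits therefore cannot tell whether the calls arose by chance. The real split gave 6902 called genes and 2346 at least 2-fold, and 1 of 10 splits was as large for each; the highest other split gave 0 for both in edgeR, where 11 to 348 genes had an unadjusted p under 0.05, 0 in limma-voom and at most 1 in DESeq2. For gene lists, the real split called 14 and the highest other also 14, and 5 of the 10 splits were as large.

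The D libraries differed along gene length. Log2 CPM was taken as deviations from the mean of the library's group. Its slope on log2 length was 0.013, 0.17 and −0.18 in D replicates 1, 2 and 3. Slopes ranged over 0.0995 in the C libraries and 0.354 in the D libraries, so length trends between libraries without a group difference stay open as a source of part of the D pattern. A difference in the extent of the change between D libraries may add to it: with length trends removed, D replicate 3 minus replicate 2 followed D replicate 1 minus C with a slope of 0.0857 (0.0759 to 0.0959), which leaves this open. The interval came from resampling genes within these libraries, so it holds no spread between libraries. The tables argue against a length trend as the cause of most calls, since 6657 of 6902 were called with the same sign once trends were removed. A length trend may account for the oxidative phosphorylation list, whose median gene length was 1236 bp. With trends removed, its mean log2 difference went from 0.22 (SD 0.29 over the D libraries) to 0.068 (SD 0.071). Its adjusted p went from 0.046 to 0.67 (camera) as the difference shrank. Each removed trend was fitted against the mean of all 6 libraries, so it also held any group difference shared by short genes. The shrinkage therefore cannot tell a technical trend from a change of short genes. GC content was not analysed here.

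For the mouse labels, 11 human-only genes with more than 3 counts in every library argued against reads counted on a mouse annotation, and no biological explanation was tested.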
